A study of Mus musculus with 19 samples.

How the data were processed

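Expression was measured on Affymetrix oligonucleotide arrays in 19 tumours, with 1 array per tumour. The tumours were mouse medulloblastomas of the genotype Ptch+/-p53-/-, grown under the skin of nude mice from cells dissociated from tumours. Per the labels' protocols, total RNA came from flash-frozen tumour tissue, biotinylated cRNA was made by the standard Affymetrix method, and animals had been randomized to groups of similar mean tumour volume. Groups were taken from the sample descriptions, which gave 3 vehicle tumours, 8 tumours treated at 40 mg/kg and 8 treated at 160 mg/kg with NVP-LDE225.

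The deposited values are signal intensities on a linear scale, made with the MAS5 algorithm per the submitters' processing notes. MAS5 sums up the probe pairs of a probe set after subtracting a local background and the mismatch signal, and it scales each array separately. The scaling target is not given in the sources used here. The mean signal after trimming 2% at each end was 150 on every array. The table holds 45101 probe sets, and the platform table that names them is that of the full-genome Mouse 430 2.0 array, whereas the series text names the smaller 430A 2.0 array. Gene names therefore rest on the platform table that lists these probe sets. No detection calls, scan dates or hybridization batches were used here, so a batch could not be tested.

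After 64 control probe sets were left out, 45037 remained, of which 34945 had 1 gene symbol, 932 had several and 9160 had none. Probe sets with several or no symbols were never used to name a gene. For 34754 of the probe sets with 1 symbol the Entrez identifier matched the GRCm38.p6 gene table, which changed 0 symbols and supplied the order of genes along chromosomes. No coordinates are printed because the array files name no genome build. Trp53 had no probe set of its own among those kept and was not analysed here, and some items are not reported here.

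Values were tested as log2 of the signal plus a pseudocount of 2.5, the 10th percentile of all values, without further normalization. Fold changes on this scale understate the change of dim genes. Probe sets were kept when they exceeded the 40th percentile of their array on at least 3 arrays, which left 31143 probe sets and 13454 genes. The tests were limma's lmFit and eBayes with a variance trend, in a single fit of 3 group means with 16 residual degrees of freedom, so the groups shared an estimate of the spread. P-values are two-sided and were adjusted by the Benjamini-Hochberg method, and a probe set was called at an adjusted p under 0.05. A gene with several probe sets was represented by the kept probe set with the highest mean over all arrays.

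The comparisons, the 25 gene lists and the rule for naming genes were fixed before the data were examined. For each comparison the rule took the 10 genes with the largest called rise and the 10 with the largest called fall, without clone-like symbols. It also took 15 Hedgehog, cell cycle and growth factor genes, and up to 4 members with the smallest p in each list. Of the lists, 15 describe pathways, cell states and sample handling and 10 describe cell types that a subcutaneous graft could hold. Lists were tested with camera at its preset inter-gene correlation of 0.01 and again with an estimated correlation. Relations across tumours were tested by exact permutation over groups of 8 and by 100000 permutations over larger sets. Differences between list means were tested by exact permutation over the 969 choices of 3 arrays.

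Arrays were compared before groups were formed. Pairwise correlations of log2 signal ran from 0.897 to 0.952, and 0 pairs were identical. Replicate numbers recur in all groups of the labels, without a statement that a number marks a shared animal or day. Deviations of same-numbered arrays from their group means were therefore correlated, and the fit without the number as a block was kept.

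The fit was tested on simulated arrays of 31143 probe sets, with 100 changed by 1 and 100 changed by 2 on the log2 scale. Values were drawn from normal distributions with the real means and the variances that eBayes estimated. Each probe set was drawn independently of the others, and tumours far from their group were not simulated. The shares that follow therefore hold for data that meet the assumptions of the fit. For the mean of both doses against vehicle, 57% of the smaller and 84% of the larger changes were called, and 5.4% of the calls were false. For 160 against 40 mg/kg, 73% and 96% were called, and 1.7% of the calls were false. The alternatives were quantile normalization, subtraction of array medians, other pseudocounts, other filters, a fit without variance trend, array weights, fits of the compared groups alone, a host tissue covariate, a replicate block, a 2-fold threshold, treated arrays as a single group, and leaving out each array. The number of arrays, 3 of them in the vehicle group, limits the precision of every comparison with vehicle. Calculations used R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.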

Results

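Gene expression was measured in 19 subcutaneous medulloblastomas, each on 1 array. The tumours came from cells of a mouse that lacked p53 and carried 1 working copy of Ptch, the receptor that holds back Hedgehog signalling, and they grew in nude mice. There were 3 tumours from vehicle-treated mice, which the labels call sensitive. The other tumours came from mice given NVP-LDE225, an antagonist of the Hedgehog signal transducer Smoothened, with 8 tumours at 40 mg/kg and 8 at 160 mg/kg, all of which the labels call resistant. The source names of 160 mg/kg tumours 6 and 7 call them resistant and those of the other treated tumours call them treated, and all were kept in their dose group. Treatment and resistance therefore form a single contrast. The median signal per array ran from 32.7 to 49.7, and the number of arrays limits the precision. Each tumour is taken as a separate sample, which the labels do not state, so p-values measure the spread between these samples.

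The first question was how resistant tumours of both doses differed from vehicle tumours. Several genes of young and maturing neurons rose. Cntn2, an adhesion molecule of young granule neurons, rose 10.1-fold, from a signal of 38.3 ± 5.92 (SD, n = 3) in vehicle tumours to 465 ± 228 (SD, n = 8) at 40 mg/kg and 438 ± 209 (SD, n = 8) at 160 mg/kg. Snap91, which helps to form synaptic vesicles, rose from 50.6 ± 8.52 (SD, n = 3) to 492 ± 246 and 534 ± 255 (SD, n = 8 each). Both genes were above all vehicle tumours in 16 of 16 treated tumours. Fabp7, a fatty acid binding protein of radial glia, rose 12-fold, and Stmn2, a microtubule regulator of growing axons, rose 8.82-fold, each above all vehicle tumours in 15 of 16. The log2 changes were 3.34 for Cntn2 (SE 0.38, adjusted p = 0.000309), 3.14 for Snap91 (SE 0.39, adjusted p = 0.000417), 3.59 for Fabp7 (SE 0.79, adjusted p = 0.0135) and 3.14 for Stmn2 (SE 0.64, adjusted p = 0.00851). In the 3 fits without 1 vehicle tumour, Cntn2 and Snap91 were called in 3, Stmn2 in 1 and Fabp7 in 0. The other genes with the largest rises by the rule were the transcription factor Uncx, the cadherin Fat2 of granule neurons, Slc35f1, the bicarbonate transporter Slc4a10, the sodium channel Scn3a and the receptor adaptor Grb14. Their mean vehicle signals, from 3.33 for Slc35f1 and Slc4a10 to 6.00 for Fat2, lay near the pseudocount of 2.5, so the size and order of these rises depend on it and no fold is given. Their means at 160 mg/kg ran from 54.0 for Grb14 to 119 for Uncx.

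Of 27 measured neuronal maturation genes, 10 rose, 0 fell and 17 did not pass the test; adjusted over the list alone 12 rose. The median log2 change was 1.02, and the list mean was above all vehicle tumours in 16 of 16 treated tumours. Besides Stmn2, the growth cone protein Gap43 rose by 1.85, the reticulon Rtn1 by 1.28 and the microtubule protein Dcx of migrating neurons by 1.06 on the log2 scale. The list was higher than other genes with camera (adjusted p = 2.19e-11), and its adjusted p = 0.264 with an estimated correlation. By exact permutation of the list means over 969 choices of 3 arrays, 0 of 25 lists passed after adjustment, with an adjusted p = 0.095 for the neuronal maturation list (unadjusted 0.0114), 0.0645 for the granule neuron precursor list (unadjusted 0.00516) and 0.0515 for the interferon list (unadjusted 0.00206). Of 18 granule neuron precursor genes, 5 rose and 0 fell; adjusted over the list alone 7 rose. These were Cntn2 and the transcription factors Neurod1 (1.22), Nhlh2 (1.05), Sox11 (0.89) and Zic1 (0.51), and the list median was 0.31 (camera adjusted p = 0.000261; adjusted p = 0.223 with an estimated correlation). Myelin and oligodendrocyte lineage markers moved partly with these lists: the tight junction gene Cldn11 of myelin rose by 2.62 (SE 0.65, adjusted p = 0.0263; called in 0 of the 3 fits without 1 vehicle tumour), 1 of 11 rose over all genes and 1 adjusted over the list alone, and the list median was 0.30 (camera adjusted p = 0.200). With the mean of all kept probe sets of a gene that median was 0.55, and the list passed the test.

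Several interferon response genes fell in resistant tumours. Ifit1, an interferon-induced protein that binds viral RNA, dropped from a signal of 608 ± 141 (SD, n = 3) in vehicle tumours to 148 ± 131 at 40 mg/kg and 69.3 ± 48.8 at 160 mg/kg (SD, n = 8 each), and lay below all vehicle tumours in 16 of 16. Oasl2, of the oligoadenylate synthetase family, fell by 2.65 on the log2 scale (SE 0.49, adjusted p = 0.00504), and Ifit1 fell by 2.85 (SE 0.53, adjusted p = 0.00513). Slfn8 fell from 153 ± 48.2 (SD, n = 3) to 41.2 ± 17.7 and 26.1 ± 5.77 (SD, n = 8 each), a log2 change of -2.15 (SE 0.27, adjusted p = 0.000417). The other genes with the largest falls were the carbonic anhydrase Car4 (-2.80), the RNA helicases Ddx60 (-2.55) and Dhx58 (-2.49), Oasl1 (-2.46), Samd9l (-2.25), the immunoproteasome subunit Psmb8 (-2.19) and the ISG15 protease Usp18 (-2.13). Dhx58 signals at 160 mg/kg (mean 11.5) lay near the pseudocount of 2.5, so the size of its fall depends on it. Of the 3 fits without 1 vehicle tumour, Ifit1, Oasl2, Slfn8 and Oasl1 were called in 3, Ddx60 and Samd9l in 1, and Car4, Dhx58, Psmb8 and Usp18 in 0. Of 18 measured interferon response genes, 12 fell and 0 rose; adjusted over the list alone 18 fell. The median log2 change was -1.52 (camera adjusted p = 1.56e-12; adjusted p = 0.264 with an estimated correlation). Macrophage and microglia markers had a median of 0.09 with 0 of 19 called by limma and 0 adjusted over the list alone (camera adjusted p = 0.497).

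**Figure D1:**
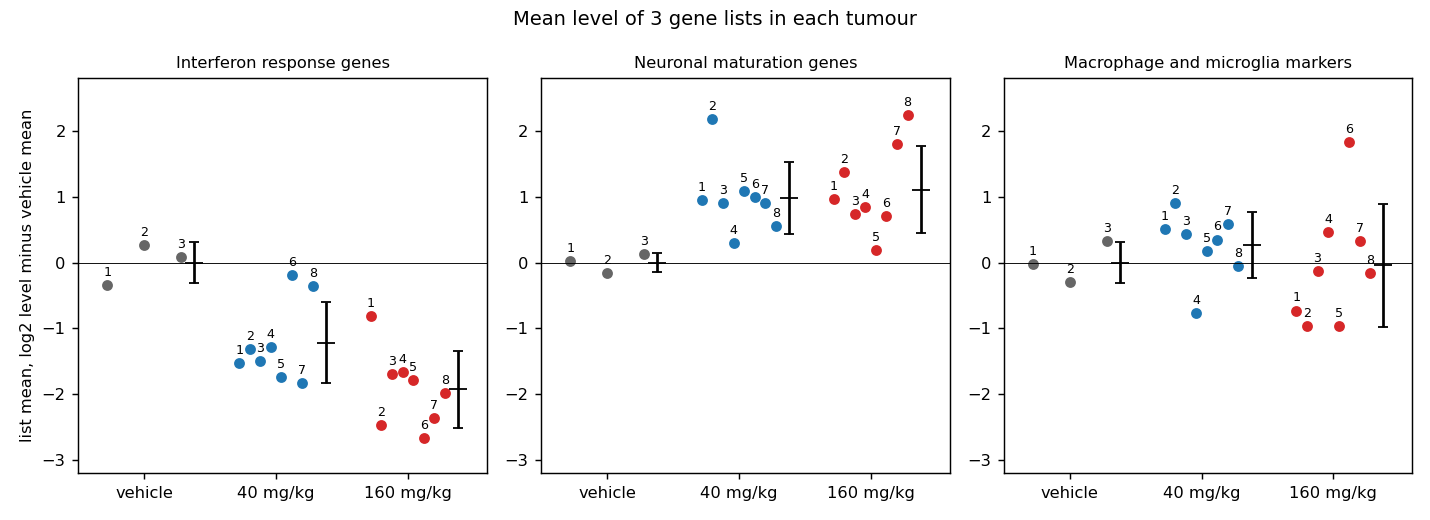
Mean log2 level of the interferon, neuronal maturation and macrophage lists minus the vehicle mean, with 1 numbered point per tumour, and bars that give the mean and SD of each group. The interferon list lay below all vehicle tumours in 15 of 16 treated tumours and the neuronal maturation list above them in 16 of 16.

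Of the Hedgehog pathway, the target of the drug, the genes Gli1 and Gli2 varied between resistant tumours. Gli1, a transcription factor and target of the pathway, had a signal of 329 ± 8.96 (SD, n = 3) in vehicle tumours and ran from 106 to 2640 in treated tumours, below all vehicle tumours in 12 and above them in 3. Gli2, the main activating factor, was 616 ± 38.3 (SD, n = 3) in vehicle tumours, 1670 ± 708 (SD, n = 8) at 40 mg/kg and 1110 ± 1340 (SD, n = 8) at 160 mg/kg, and was above all vehicle tumours in 9. The highest Gli1 signals were 2286 in 40 mg/kg tumour 8 and 2638 in 160 mg/kg tumour 1, and the highest Gli2 signal was 4326 in 160 mg/kg tumour 2. No mean change passed the test: the log2 changes were -0.35 for Gli1 (SE 0.77, adjusted p = 0.821), 0.78 for Gli2 (SE 0.54, adjusted p = 0.407) and -0.61 for the receptor Ptch1 (SE 0.30, adjusted p = 0.239). The inhibitor Hhip had -0.75 (adjusted p = 0.442), Gli3 -0.72 (adjusted p = 0.138), Smo, the target of the drug, -0.59 (adjusted p = 0.0673) and Sufu -0.48 (adjusted p = 0.0611). A second Smo probe set did pass (log2 change -0.65, adjusted p = 0.0382). Ptch1, Smo and Sufu were each below all vehicle tumours in 15 of 16 treated tumours, and Gli3 in 14. Hhip was below them in 10 and above them in 3. Smo and Sufu lie near the threshold: the Smo log2 fold change, resistant versus vehicle, passed with quantile normalization (adjusted p = 0.0468) and with array weights (0.000673), against 0.0673 as deposited. Smo also passed with the replicate block (-0.80), without 40 mg/kg tumour 4 and without 160 mg/kg tumour 6. Sufu passed with the filter at the 60th percentile, with array weights (-0.54), without 40 mg/kg tumour 6 and without 160 mg/kg tumour 2. Neither passed under the remaining alternatives. Among 18 Hedgehog target genes 14 were lower and 4 higher. With limma 0 of them were called, 0 adjusted over the list alone, and the median was -0.38 (camera adjusted p = 0.344). Among 24 pathway components the kinase Gsk3b rose by 0.73 and the coreceptor Gas1 fell by 1.03; adjusted over the list alone 1 rose and 4 fell (median -0.04, camera adjusted p = 0.565).

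**Figure D2:**
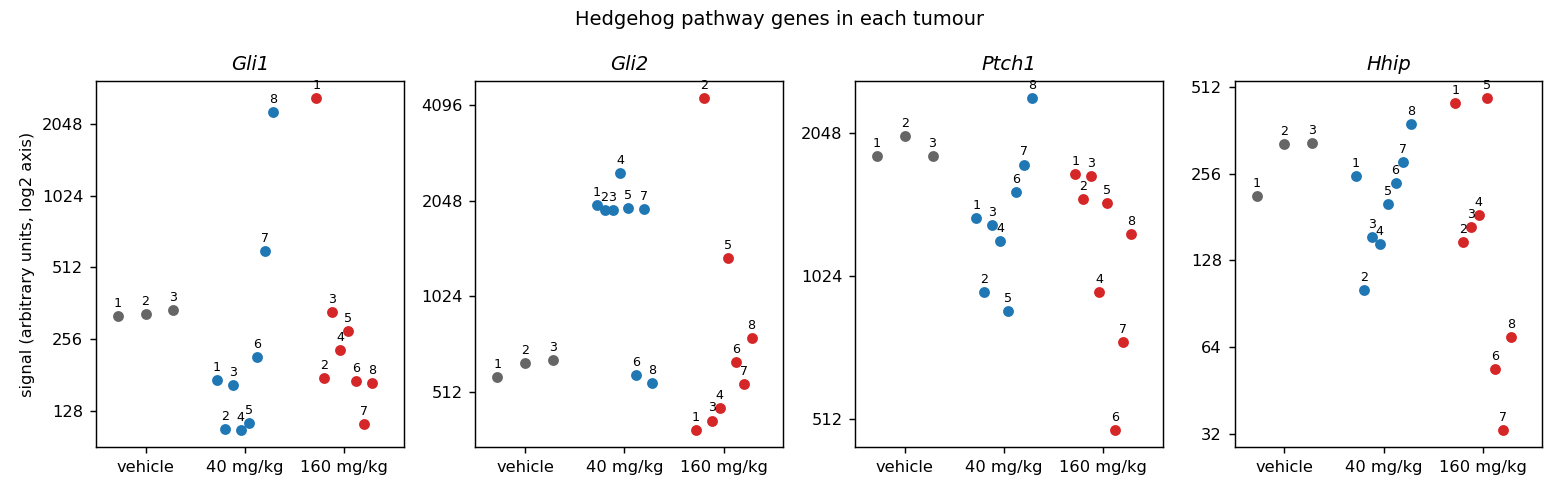
Signal of Gli1, Gli2, Ptch1 and Hhip on log2 axes that differ in range, with 1 numbered point per tumour and the tumours grouped by treatment. Gli1 ran from 106 to 2640 in treated tumours, against a vehicle mean of 329.

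Growth factor and other signalling genes mostly did not pass the test. Igf1r, the receptor of insulin-like growth factors, had a log2 change of -0.72 (SE 0.26, adjusted p = 0.113), Igf2 1.32 (SE 0.85, adjusted p = 0.374), the kinase subunit Pik3r1 0.19 (adjusted p = 0.556), Mycn -0.19 (adjusted p = 0.623) and the cell cycle gene Ccnd1 -0.51 (SE 0.19, adjusted p = 0.124). Igf1r passed without 160 mg/kg tumour 6 (log2 change -0.80), and Igf1r (-0.74), Ccnd1 (-0.44) and Ptch1 (-0.58) passed with array weights. Of 37 PI3K and IGF signalling genes the transcription factor Foxo1 fell by 0.92 and 0 rose; adjusted over the list alone 2 rose and 1 fell (median 0.06, camera adjusted p = 0.350). Of 37 mitotic and DNA replication genes the spindle motor Kif11 fell by 0.53, 3 fell adjusted over the list alone, and the median was -0.17 (camera adjusted p = 0.00674; adjusted p = 0.750 with an estimated correlation). Without vehicle tumour 2 that median was -0.11 and the list did not pass. Hypoxia genes had a median of 0.33 with 0 of 19 called by limma, 0 adjusted over the list alone (camera adjusted p = 0.000729; adjusted p = 0.682 with an estimated correlation). Of 20 p53 target and apoptosis genes the stress gene Gadd45a rose by 1.56 and the cell death gene Bcl2l11 fell by 0.81; adjusted over the list alone 1 rose and 3 fell (median 0.11, camera adjusted p = 0.497). Ier3 rose by 1.16 among 17 immediate early genes, 1 adjusted over the list alone (median 0.22, camera adjusted p = 0.112). Without vehicle tumour 3 the median of that list was 0.38 and it passed, and without vehicle tumours 1 and 2 in turn it was 0.04 and 0.11 and did not. Cyp1b1, an oxidizing enzyme, rose by 2.00 among 12 drug efflux and detoxification genes, 1 adjusted over the list alone (camera adjusted p = 0.565). That list had a median of -0.04 and a mean of 0.16, with the test pointing up. In the 3 fits without 1 vehicle tumour, Gadd45a was called in 1, and Foxo1, Kif11, Bcl2l11, Ier3 and Cyp1b1 in 0. Notch signalling genes had a median of -0.07 and a mean of 0.16, with the test pointing up; 0 of 15 were called by limma, and adjusted over the list alone 2 rose and 1 fell (camera adjusted p = 0.663). In the remaining pathway lists 0 genes were called by limma and 0 adjusted over the list alone: RAS and MAPK feedback genes had a median of -0.08 (camera adjusted p = 0.690), Wnt target genes -0.21 (0.753) and cholesterol synthesis genes 0.05 (0.554).

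Markers of other cell types were tested because a graft under the skin holds host tissue. Of 14 astrocyte and radial glia markers Fabp7 and Aldoc rose and the gap junction gene Gja1 fell by 1.40; adjusted over the list alone 3 rose and 3 fell. That list had a median of -0.24 and a mean of 0.22, with the test pointing up (camera adjusted p = 0.823). Flt1, a receptor of vascular growth factors, fell by 0.71 among 15 endothelial markers, 1 adjusted over the list alone (median -0.19, camera adjusted p = 0.432). The matrix enzyme Loxl1 fell by 1.20 among 19 fibroblast and matrix markers, 1 adjusted over the list alone (median -0.37, camera adjusted p = 0.565). Skeletal muscle markers had 0 of 18 called by limma and 0 adjusted over the list alone (median -0.55, camera adjusted p = 0.554), and skin epithelium markers 0 of 6 and 0 (median -0.41, camera adjusted p = 0.432). Adipocyte markers had 0 of 8 called by limma and 1 that fell adjusted over the list alone (median -0.73, camera adjusted p = 0.344), lymphocyte markers 0 of 3 and 1 (median -0.48, camera adjusted p = 0.432), and erythroid markers 0 of 3 and 0 (median -0.92, camera adjusted p = 0.565). At an unadjusted p under 0.05, 6686 of all probe sets passed.

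**Figure D3:**
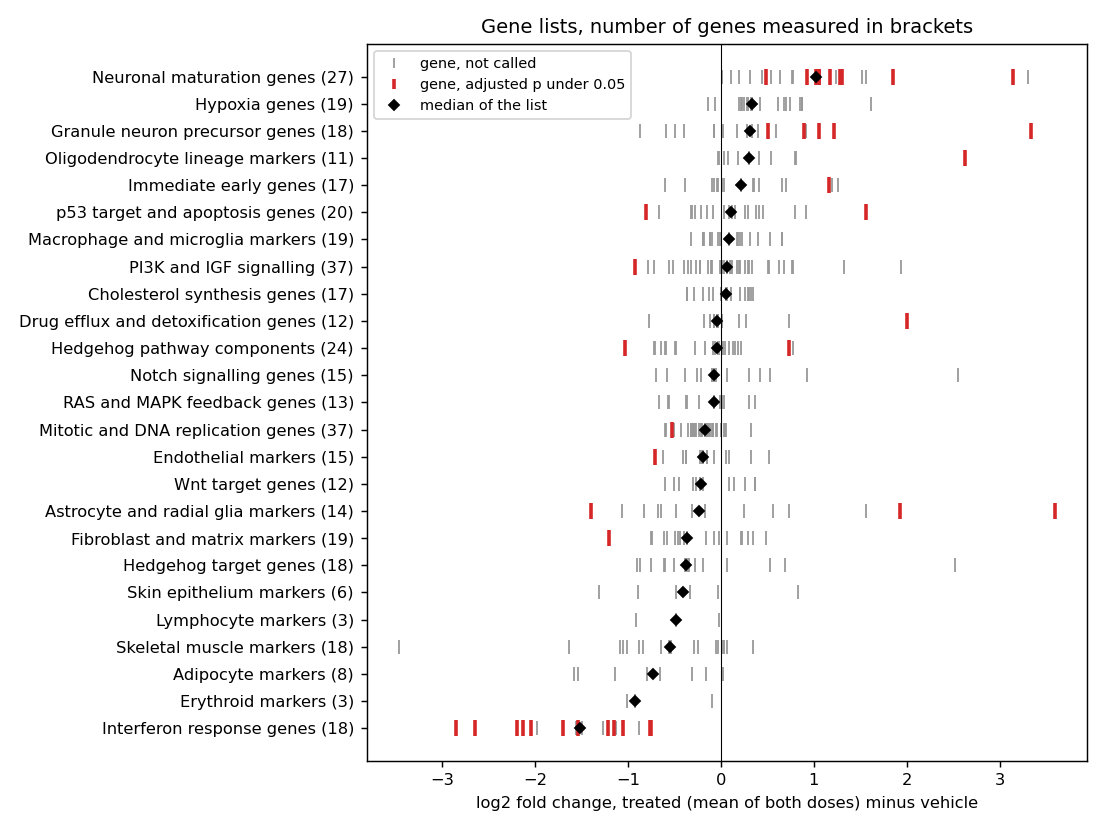
Log2 change of treated tumours (mean of both doses) against vehicle for each gene of each list, as ticks that are red where the adjusted p was under 0.05, with the list median as a diamond and the number of measured genes in brackets. The neuronal maturation list had a median of 1.02 and the interferon list of -1.52.

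In the comparison NVP-LDE225 resistant (mean of both doses) versus vehicle, limma called 1392 of 31143 probe sets, 822 higher and 570 lower, for 712 genes, of which 382 were higher and 330 lower. Of these probe sets 554 changed at least 2-fold. The calls depend on the 3 vehicle tumours: 425, 472 and 243 remained in number without vehicle tumours 1, 2 and 3, 274 without the 2 arrays least like the others (vehicle tumour 3 and 160 mg/kg tumour 2), 819 with the replicate number as a block, and 8907 with array weights. Subtracting array medians changed the split to 825 higher and 199 lower, and 13 of 41 named calls held in all 19 fits without 1 array: Cntn2, Dcx, Grb14, Ifi35, Ifit1, Nhlh2, Oasl1, Oasl2, Scn3a, Slc35f1, Slfn8, Snap91 and Sox11. Bcl2l11 held in 14 of these fits, Ier3 in 11, Cyp1b1 in 9, Kif11 in 6 and Aldoc in 4.

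At 40 mg/kg the question was which genes differ from vehicle at the lower dose. Cntn2 rose by 3.38 on the log2 scale (SE 0.41, adjusted p = 0.000601), Nalcn, a sodium leak channel of neurons, by 3.16 (SE 0.49, adjusted p = 0.00301), Fabp7 by 3.69 (SE 0.85, adjusted p = 0.0268) and Cldn11 by 3.10 (SE 0.70, adjusted p = 0.0235). Ifit1 fell by 2.39 (SE 0.57, adjusted p = 0.0323), Slfn8 by 1.88 (SE 0.29, adjusted p = 0.0032) and Car4 by 2.50 (adjusted p = 0.0451). In the 3 fits without 1 vehicle tumour, Cntn2, Nalcn and Slfn8 were called in 3, and Fabp7, Cldn11, Ifit1 and Car4 in 0. Of 18 interferon response genes 4 fell and 0 rose; adjusted over the list alone 14 fell (median -1.13, camera adjusted p = 2.38e-08; adjusted p = 0.563 with an estimated correlation). Of 27 neuronal maturation genes 5 rose and 0 fell; adjusted over the list alone 10 rose (median 0.92, camera adjusted p = 2.85e-09; adjusted p = 0.440 with an estimated correlation). Of 18 granule neuron precursor genes 5 rose; adjusted over the list alone 6 rose (median 0.27, camera adjusted p = 0.000255; adjusted p = 0.244 with an estimated correlation). Hypoxia genes had 0 called by limma and 3 that rose adjusted over the list alone (median 0.54, camera adjusted p = 7.23e-05; adjusted p = 0.565 with an estimated correlation), and mitotic genes 0 and 0 (median -0.23, camera adjusted p = 0.00144; adjusted p = 0.603 with an estimated correlation). At an unadjusted p under 0.05, 6015 of all probe sets passed.

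For 40 mg/kg NVP-LDE225 versus vehicle, limma called 668 probe sets, 472 higher and 196 lower, for 343 genes. The count was 194, 194 and 120 without vehicle tumours 1, 2 and 3, 443, 418 and 439 without 40 mg/kg tumours 1, 2 and 7, 169 without the 2 arrays least like the others, 324 with the replicate block, 1553 in a fit of the compared groups alone, and 7452 with array weights. Subtracting array medians gave 454 higher and 74 lower, and 7 of 30 named calls held in all 19 fits without 1 array (Ifit1 in 12, Car4 in 7).

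At 160 mg/kg the same question was asked of the higher dose. Cntn2 rose by 3.29 on the log2 scale (SE 0.41, adjusted p = 0.000499) and Gap43 by 2.08. Uncx rose from a signal of 5.57 ± 6.90 (SD, n = 3) to 119 ± 66.7 (SD, n = 8; limma adjusted p = 0.0174) and Slc35f1 from 3.33 ± 2.75 (SD, n = 3) to 83.2 ± 80.6 (SD, n = 8; limma adjusted p = 0.00211), with vehicle signals too near the pseudocount for a fold. In the 3 fits without 1 vehicle tumour, Cntn2, Slc35f1 and Ifit1 were called in 3, and Gap43 and Uncx in 1. Ifit1 fell by 3.32 (SE 0.57, adjusted p = 0.00287), and the other large falls were of Oasl2 (-3.14), Car4 (-3.10), Dhx58 (-3.08), Ddx60 (-3.01) and Psmb8 (-2.82). Of 18 interferon response genes 16 fell and 0 rose; adjusted over the list alone 18 fell (median -1.88, camera adjusted p = 7.11e-16; adjusted p = 0.164 with an estimated correlation). Of 27 neuronal maturation genes 11 rose and 0 fell; adjusted over the list alone 12 rose (median 1.04, camera adjusted p = 4.92e-12; adjusted p = 0.164 with an estimated correlation). Of 18 granule neuron precursor genes 5 rose, also 5 adjusted over the list alone (median 0.21, camera adjusted p = 0.000412; adjusted p = 0.164 with an estimated correlation). Hypoxia genes (median 0.21, camera adjusted p = 0.0178) and mitotic genes (median -0.19, camera adjusted p = 0.0475) had 0 called by limma and 0 adjusted over the list alone, each with an adjusted p = 0.752 with an estimated correlation. Of single genes, Gas1 fell by 1.30, Foxo1 by 1.04, the Notch target Hes1 by 0.84 and the apoptosis protease Casp8 by 0.84. Hes1 was the only one called of 15 Notch signalling genes. Adjusted over that list alone 1 rose and 1 fell (median -0.19, camera adjusted p = 0.859). Gli2 had a log2 change of 0.31 (adjusted p = 0.797) and Igf1r of -0.97 (SE 0.28, adjusted p = 0.0538). At an unadjusted p under 0.05, 6354 of all probe sets passed.

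For 160 mg/kg NVP-LDE225 versus vehicle, limma called 1260 probe sets, 708 higher and 552 lower, for 658 genes. The count was 453, 572 and 217 without vehicle tumours 1, 2 and 3, 220 without the 2 arrays least like the others, 629 in a fit of the compared groups alone, and 6145 with array weights. Subtracting array medians gave 818 higher and 227 lower, and 12 of 37 named calls held in all 19 fits without 1 array (Casp8 in 7).

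Both doses were compared with the same vehicle tumours, and 506 probe sets were called at both, 376 higher and 130 lower. Across probe sets, which are not independent replicates, the log2 changes at the 2 doses correlated with r = 0.876, against 0.727 in simulated data without an effect and with the same shared controls. Simulated data gave at most 1 probe set called at both doses. The simulation drew each probe set independently, whereas real genes vary together (estimated correlation 0.642 in the interferon list). It therefore cannot say how many shared calls, or how high an r, chance would give here.

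The last comparison asked whether the doses differ. Interferon response genes were lower at 160 than at 40 mg/kg in 18 of 18 members, with a median log2 difference of -0.71. With limma 0 were called, and adjusted over the list alone 9 fell (camera adjusted p = 2.28e-11, and adjusted p = 0.512 with an estimated correlation). The tumours of the doses overlapped: list means ran from -1.84 to -0.19 at 40 mg/kg and from -2.67 to -0.82 at 160 mg/kg. Ifit1 signals ran from 43.7 to 376.5 and from 18.8 to 177. Macrophage and microglia markers were also lower in 18 of 19 members, with a median of -0.29, and did not pass (camera adjusted p = 0.0662; adjusted p = 0.514 with an estimated correlation). Muscle markers had a median of -1.28 (camera adjusted p = 0.00156), fibroblast and matrix markers -0.40 (camera adjusted p = 0.000513), Notch signalling genes -0.26 (camera adjusted p = 0.0196) and hypoxia genes -0.26 (camera adjusted p = 0.0276), each with an adjusted p = 0.661 with an estimated correlation and 0 members called adjusted over the list alone. PI3K and IGF signalling genes had a median of -0.16 with 0 called adjusted over the list alone (camera adjusted p = 0.0349; adjusted p = 0.512 with an estimated correlation). Gli2 had a difference of -0.95 (SE 0.43, adjusted p = 0.711) and Igf1r of -0.49 (adjusted p = 0.693). For 160 versus 40 mg/kg NVP-LDE225, limma called 0 probe sets, with 2122 at an unadjusted p under 0.05, where 1557 would fall by chance; a fit without a variance trend called 1.

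Relations between genes across resistant tumours were tested in a family of 24. Gli1 and its target Ptch1 had a Spearman rho of 0.78 over 16 treated tumours (permutation p = 0.0006, adjusted p = 0.014) and a Pearson r of 0.65 (permutation p = 0.009, adjusted p = 0.11). Without the 2 tumours farthest from the median of Gli1, r was 0.56 (permutation p = 0.041, adjusted p = 0.31) and rho 0.68 (permutation p = 0.0087, adjusted p = 0.07) over 14 tumours. Within the 40 mg/kg group r was 0.91 (exact p = 0.00027, adjusted p = 0.0065) and rho 0.90 (exact p = 0.0046, adjusted p = 0.055). Within the 160 mg/kg group r was 0.53 (exact p = 0.16, adjusted p = 0.42) and rho 0.79 (exact p = 0.028, adjusted p = 0.17). For Gli2, the treated tumours were parted at the widest gap in its log2 level, 0.83, into 8 lower and 8 higher tumours. No pooled value is given, although the plan named all 16 treated tumours and each dose group. Parting by the level of Gli2 narrows its range, so the values within the parts cannot decide whether Gli2 is related to another gene. The next gap, of 0.79, sets 160 mg/kg tumour 2 apart, so the parting is not the only one the values allow. With Gli1, Gli2 had r = -0.50 in the lower tumours (rho = -0.64) and -0.23 in the higher (rho = -0.17), with permutation adjusted p = 0.42 and 0.64. The relations of Gli1 with the proliferation gene Mki67, the PI3K list and the neuronal list, and of Ccnd1 with its neighbours, had adjusted p of 0.42 or more for r.

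The level of Gli2 was compared with that of its neighbours on chromosome 1, a comparison planned for Gli2 and Ccnd1 over all treated tumours and within each dose group. In 40 mg/kg tumours 1, 2, 3, 4, 5 and 7 and in 160 mg/kg tumour 5, the mean of 20 neighbours lay 0.81, 0.92, 0.82, 1.13, 1.42, 1.10 and 0.74 above the vehicle mean on the log2 scale. Gli2 in the same tumours lay 1.69, 1.63, 1.64, 2.02, 1.66, 1.65 and 1.13 above it. Gli2 lay 2.81 above it in 160 mg/kg tumour 2, where the neighbours lay -0.14 from it. Tmem185b and Ptpn4, chosen after their values were seen, lay 2.10 and 2.11 above the vehicle mean in 160 mg/kg tumour 5, and 0.15 and -0.06 from it in 160 mg/kg tumour 2. In 40 mg/kg tumour 5, where Gli2 lay 1.66 above the vehicle mean, Tmem185b lay 2.83 above it. Sctr, chosen in the same way, lay -0.70 from it in that tumour. The neighbours thus moved unequally, and their mean cannot show that Gli2 rose further than its region. Within the lower and the higher tumours, Gli2 and the neighbour mean had r = 0.70 in the lower (rho = 0.52, exact p = 0.052, adjusted p = 0.31) and -0.64 in the higher (rho = 0.02, exact p = 0.14, adjusted p = 0.42). Because this parting, unlike the plan, used the level of Gli2 itself, these r cannot decide whether Gli2 follows its neighbours. The higher tumours also include 160 mg/kg tumour 2, with the highest Gli2 and the lowest neighbour mean among them.

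**Figure D4:**
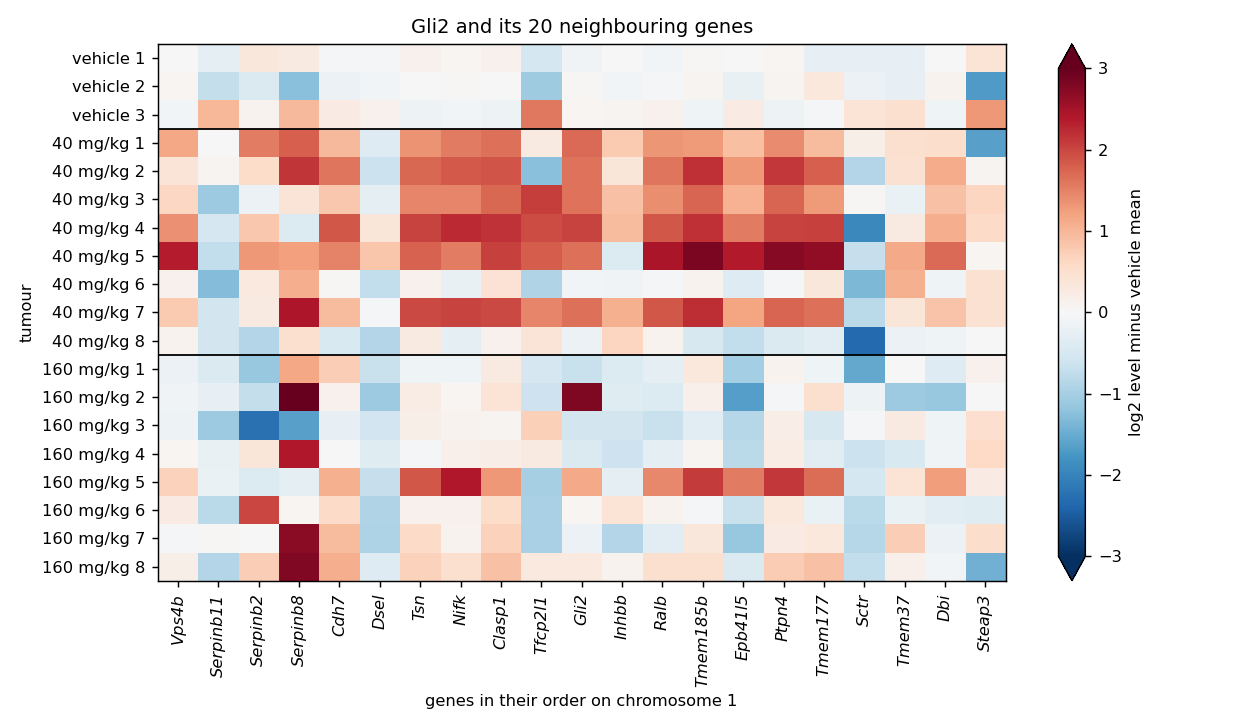
Log2 level minus the vehicle mean, as colour, of Gli2 and its 20 neighbours in their order along chromosome 1 (columns) in each tumour (lines of the map). In 160 mg/kg tumour 2 Gli2 lay 2.81 above the vehicle mean while the mean of the neighbours was -0.14.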

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

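The tests of Gli2, of macrophages, of host share and of nerve were chosen only after the results were seen. The splits of the arrays, and the leaving out of single arrays for the medians of the interferon and neuronal maturation lists, were planned. Of 132 groups of 8 tumours, 21 held a tumour set apart by Dixon's test of the gap to its neighbour. The usual chance rate of about 1 in 20 holds for independent groups of normal values. Genes were tested on the linear signal, and the groups share tumours, so that rate does not apply here.

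Chance is argued against as the source of the counts against vehicle, though not excluded, since 100 splits of the arrays can give no p under 0.01. Among these splits, 1, the real one, gave as many for both doses (1392, highest other 72). The same held for 40 mg/kg (668, highest other 20) and for 160 mg/kg (1260, highest other 80), with 1 split each. For 160 against 40 mg/kg, with 0 called by limma and 2122 at an unadjusted p under 0.05, 100 of 100 splits gave as many (highest other 23). A count of 0 is reached by every split by construction, so this says nothing about chance, and the unadjusted count was not tested on splits.

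Gli2 stood far above the other 160 mg/kg tumours in 160 mg/kg tumour 2 (4326, next 1348) and was high in 7 further treated tumours. An error of 1 probe set is argued against by the second Gli2 probe set, which was raised by over 0.8 in 8 of 8, and array scaling by a largest median shift of 0.093 in size. A gain of a wide chromosome region may account for the 7 further tumours, since their 20 neighbours lay above the 99th percentile of runs of 20 genes in 7 of 7, against 0 of the 8 tumours with lower Gli2. For 160 mg/kg tumour 2 that percentile was 35.4, too low for a wide gain. DNA was not analysed here, so a narrow gain and regulation of the gene stay open.

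Interferon response genes were lower in treated tumours with camera at its preset correlation (adjusted p = 0.264 with an estimated correlation; exact permutation of list means, adjusted p = 0.0515), and their median at 160 against 40 mg/kg was -0.71, with 0 of 18 called by limma (9 adjusted over the list alone) and adjusted p = 0.512 with an estimated correlation. For treated against vehicle tumours, fewer macrophages are argued against, since the macrophage list had a mean change of 0.11 and the interferon list lay -1.69 from it (unadjusted exact p = 0.0289), and a single array by a median of -1.30 closest to 0 over 19 fits. Between the doses the means of the interferon list overlapped (-1.84 to -0.19 at 40 mg/kg, -2.67 to -0.82 at 160 mg/kg). Macrophage markers were lower at 160 mg/kg in 18 of 19 members (median -0.29, camera adjusted p = 0.0662), so fewer macrophages stay open for the difference between the doses. Less interferon in the host, a direct effect of the drug and a change in tumour cells stay open as untested hypotheses.

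Neuronal maturation genes were higher in treated tumours with camera at its preset correlation (adjusted p = 0.264 with an estimated correlation; exact permutation of list means, adjusted p = 0.095), and 40 mg/kg tumour 2 stood apart from its dose group (list mean 2.18, next in that group 1.09; highest at 160 mg/kg 2.25). A lower share of host cells as the only cause is argued against by a difference of 1.25 from the mitotic list (unadjusted exact p = 0.0155). The mitotic list itself lay -0.21 from vehicle, so this difference cannot exclude that host share played a part. Marker means were lower for adipocytes (-0.77), erythroid cells (-0.67), muscle (-0.66), lymphocytes (-0.47), skin (-0.37), fibroblasts (-0.25) and endothelium (-0.17), and higher for macrophages (0.11). None of these passed after adjustment. A single array is argued against by a median of 0.88 closest to 0 over 19 fits. Host nerve with myelin cannot be told apart. The tumours grew under the skin, and the list tested holds markers of oligodendrocytes, a cell type of the brain, so it cannot decide this. The mean of that list was above all vehicle tumours in 7 of 16 treated tumours and Cldn11 rose. The list passed with the mean of all kept probe sets of a gene (median 0.55). A more mature state of the tumour cells may be present but was not tested apart from host nerve.

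The remaining values set apart among the 132 groups tested are given without explanation. Not all named genes were among these groups, so other values may lie as far apart. Gli1 was 2286 in 40 mg/kg tumour 8 (next 598.2) and 2638 in 160 mg/kg tumour 1 (next 331.4). In 40 mg/kg tumour 6, Sufu was 343.4 and Igf2 2521. Mycn was 1590 and Igf1r 549.3 in 160 mg/kg tumour 6. In 40 mg/kg tumour 2, Fat2 was 264.6 and Slc4a10 258.3. Slc35f1 was 276.6 in 160 mg/kg tumour 2, and Grb14 132.7 and Cldn11 500.5 in 160 mg/kg tumour 8. Ifit1 was 177, Oasl2 197.5, Usp18 287 and Ifitm3 959.9 in 160 mg/kg tumour 1. Fat4 was 45.8 in 40 mg/kg tumour 7. In 40 mg/kg tumour 5 the RAS and MAPK list mean was -0.69 and the cholesterol list mean 0.49, and in 160 mg/kg tumour 7 the muscle list mean was 1.80.

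The doses differed with camera at its preset correlation in median log2 for the interferon list above, PI3K and IGF signalling genes (-0.16), Notch signalling genes (-0.26), hypoxia genes (-0.26), fibroblast and matrix markers (-0.40) and muscle markers (-1.28), and 0 of these held with an estimated correlation.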

How the results depend on the processing

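Leaving out the 2 arrays least like the others was chosen after seeing the data. So was leaving out single arrays in the list tests, beyond the medians of the interferon and neuronal maturation lists. The other alternatives were planned. For NVP-LDE225 resistant (mean of both doses) versus vehicle (1392 called), counts were 8907 with array weights, 819 with the replicate block, 554 at 2-fold or more, 274 without the 2 arrays, and 243 to 1662 without 1 array. For 40 mg/kg NVP-LDE225 versus vehicle (668), they were 7452, 324, 341, 169, and 120 to 915, and 1553 with only the groups compared. For 160 mg/kg NVP-LDE225 versus vehicle (1260), they were 6145 with array weights, 550 at 2-fold or more, 220 without the 2 arrays, 217 to 1544 without 1 array, and 629 with only the groups compared. For 160 versus 40 mg/kg NVP-LDE225, limma called 0 (2122 at an unadjusted p under 0.05) and 1 without a variance trend, and 0 to 0 without 1 array. Array weights put 5.46 on vehicle tumour 1 against 0.984 and 0.581 on the other vehicle tumours, so that 1 array sets the vehicle mean. Fewer vehicle arrays and the stricter threshold lower counts by construction; for the other alternatives the cause was not tested. In the gene list tests 5 lists were called, 0 with an estimated correlation and 4 to 6 without 1 array, where the mitotic list lost its call without vehicle tumour 2 (median -0.11) and the immediate early list gained one without vehicle tumour 3 (median 0.38). Quantile normalization reversed "Ccnd1 with mean of Ccnd1 neighbours, 160 mg/kg" to r = 0.13 from -0.06, and "Gli1 with mean of PI3K and IGF signalling list, without the 2 farthest on x" to 0.04 from 0.00. Of 921 values under the alternatives, 900 kept their side of the threshold, 6, all of lists, lost the call and 15 gained it. These values were of the lists and of the genes from Gli1 to Pik3r1 named in every comparison, and 0 of these genes were called over both doses. Direction was compared for the genes and for lists called in either fit, and 0 of these turned. It was not compared for lists called in neither fit. Of the named genes called over both doses, 25, 18 and 13 of 41 were called without vehicle tumours 1, 2 and 3, 13 in all 19 fits without 1 array, and 36 in all 16 fits without 1 treated array; at 40 mg/kg these were 7 and 22 of 30, and at 160 mg/kg 12 and 34 of 37. The oligodendrocyte lineage list was called with the mean of all kept probe sets of a gene (median 0.55, against 0.30). Same-numbered arrays of different groups had r between -0.13 and 0.09 over 14 pairs, and 0 of 19 arrays were closest to their own number, so the numbers were not taken to pair samples. Dim genes near the background limit what can be called.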

Other observations

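The scan of chromosome regions was chosen only after the Gli2 results were seen. Runs of 17 genes in order along a chromosome, compared with 200 shuffled gene orders of each array, gave 20 runs beyond all shuffles, of which 13 lay away from Gli2 in 7 of 16 treated tumours, and 0 of the 3 vehicle tumours, each set against the other 2, held one, a number too small to compare with the treated tumours. Of these 13, 4 lay elsewhere on chromosome 1, in 40 mg/kg tumour 4 and 160 mg/kg tumour 5, which also hold a run with Gli2, and runs on other chromosomes occurred in 6 treated tumours. In 40 mg/kg tumour 8, the tumour with high Gli1 at that dose, genes of chromosome X around Fam120c had a median of 1.76 above vehicle on the log2 scale (most extreme shuffle 0.70), with 17 of 17 genes higher. In 160 mg/kg tumour 3, genes of chromosome 16 around Lsamp had a median of 1.68 (most extreme shuffle 0.92), with 15 of 17 on the same side. In 160 mg/kg tumour 2, genes of chromosome 19 around Stambpl1 had a median of -1.37 (most extreme shuffle 1.21 in size), with 16 of 17 on the same side. Those of chromosome 11 around 1700020L24Rik had a median of -1.54 in that tumour, with 15 of 17 on the same side. Genes of chromosome 13 around Fbp1 had a median of -1.17 (most extreme shuffle 1.08 in size) in 160 mg/kg tumour 6, with 14 of 17 on the same side. The genes named were chosen after their values were seen. Shuffling breaks up neighbouring genes that vary together, and DNA was not analysed here. A run beyond all shuffles therefore need not be a gain or loss of DNA.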
